A study of Mus musculus with 21 samples.

How the data were processed

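Smooth muscle cells cultured from the aorta of male C57BL/6J mice were profiled on Affymetrix mouse arrays of 45101 probe sets, with 1 array for each of 21 samples. Per the submitters' processing notes the deposited values are linear signal intensities from GCOS 1.4, and each array has a mean of 500.0 after removal of the highest and lowest 2 percent of probe sets. The summarization method, the background correction and the detection filter are not given in the sources used here. The signal medians, the 3'/5' ratios of the control probe sets for Gapdh (0.713 to 0.785) and Actb (1.191 to 1.528), and the share of the signal held by the 100 highest probe sets (5.26 to 6.24 percent) were checked for each array.

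The groups follow the labels: PBS control, antibody to LTBR, TNF, and both agonists, at 2, 6 or 24 h. The replicate numbers 0 to 3 were taken from the labels, which do not say whether they stand for separate cultures or animals, so the p-values measure only the spread between these samples. A check of the log2 values, with the group means removed, asked whether the numbers pair the arrays at 24 h. The 21 pairs of arrays with the same number correlated at 0.46 to 0.81 (median 0.63), and the 63 other pairs at -0.58 to 0.21 (median -0.23). Of 15 arrays 15 correlated best with an array of their own number. The first principal component held 32.1 percent of the variance, of which 99 percent lay between numbers, and the third held 12.3 percent, of which 84.8 percent lay between groups. The numbers thus pair the arrays. Values with the number as a block are given beside the results where the block changes a call or moves a count by more than 1.5 times. Counts of list members with the block are given only for lists named in a comparison. For lists the block changed no other call with the preset correlation, and calls it changed with an estimated correlation are given with the lists.

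Signals were used as deposited, without a further normalization, as log2(signal + 10.2), where 10.2 is the 10th percentile of all values at 24 h. A probe set was tested if its signal was above the median of its own array on at least 3 of the 15 arrays at 24 h, and 25110 passed. Control probe sets, 64 in number, were left out. Of the probe sets 34945 carry 1 gene symbol, 932 carry several and 9160 have none listed. Gene tests used the probe set with the highest mean for each of 12446 genes, and the 3246 passing probe sets without 1 gene name were tested apart.

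Genes were tested with limma 3.58.1 in R 4.3.3, in 1 fit of the 15 arrays with a variance trend and 11 residual degrees of freedom (8 with the block). A call is an adjusted p under 0.05 (Benjamini-Hochberg, over the genes of a comparison). The 7 comparisons were each treatment against the control, the combination against each single agonist, TNF against the antibody, and the interaction. The fit without the block, the comparisons, the lists, the rule for named genes and most other settings were chosen before the data were examined.

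The named genes were, for each treatment against the control, the 10 largest rises and the 5 largest falls among called genes whose treated arrays all lie above or all below the control arrays. The 5 largest rises and falls were taken in the same way for the other pairs of groups. To these were added up to 4 members of each list with the smallest adjusted p in the combination, every tested organizer gene, and the 5 largest rises and 3 largest falls for each agonist at 2 h and 6 h among genes whose higher array is above its own median.

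The 21 lists, fixed from general knowledge, held lymphoid tissue organizer genes, inflammatory chemokines, NF-kB feedback and target genes, NF-kB subunits and kinase regulators, TNF superfamily ligands and receptors, MHC class I and class II antigen presentation, interferon-stimulated genes, smooth muscle contractile genes, extracellular matrix genes, matrix proteases and inhibitors, complement and acute phase genes, cell cycle genes, sterol synthesis and uptake genes, immediate early genes, unfolded protein and oxidative stress genes, and markers of macrophages and monocytes, endothelium, lymphocytes, adventitial fibroblasts and adipocytes. The organizer list shares 2 genes with the NF-kB subunits and 4 with the TNF superfamily. Each list was tested against the other genes with camera from limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 147 pairs of list and comparison. Of these, 59 were called with the preset correlation, 29 with an estimated correlation and 63 with the preset correlation and the block. The test fry, which does not compare a list with other genes, called 33. A list p is adjusted over these pairs, and a member count adjusted over the list alone is adjusted over the tested genes of that list.

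At 2 h and 6 h the log2 difference of each treated array from the control array of the same time was taken, and each list median was ranked among 10000 random lists of the same size matched on mean expression. Calls shared between the single agonists were compared with n1 x n2 / N, with 20 simulations of unchanged groups against the same controls, and with the controls divided into pairs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

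The tests were tested on simulated data in which 50 genes were changed by each of 4 sizes in the combination against the control. Without the block 24, 74, 86 and 100 percent of the genes changed by 0.5, 1, 2 and 4 on the log2 scale were called, and 0 of 12246 unchanged genes. With the block these shares were 68, 88, 100 and 100 percent, with 9 unchanged genes called. Of the lists, 2 of 2 changed and 0 of 50 unchanged were called. The simulated values held the number effects of the blocked fit and noise drawn independently for each gene. The higher shares with the block thus follow from the way the data were simulated. As the unchanged lists were random genes, their count does not show how often lists of correlated genes are called.

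The other settings chosen at the outset were no pseudocount or one of 36, the 25th percentile; no filter or a filter on the mean; quantile normalization or scaling to equal medians; no variance trend; only the arrays of the groups compared; the replicate block; the arrays numbered 1 to 3 alone; all probe sets or the mean of a gene's probe sets; leaving out each array in turn; and, for lists, an estimated correlation and fry. The arrays numbered 1 to 3 with the block, the shared calls with the block, the controls matched by number, and the block combined with another scaling or without each array were added after the data were seen.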

Results

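Gene expression was measured in cultured smooth muscle cells from the mouse aorta, the contractile cells of the vessel wall, on 21 Affymetrix arrays of 45101 probe sets. The cells received PBS as the control, an agonist antibody to the lymphotoxin beta receptor (LTBR) at 10 µg/ml, tumour necrosis factor alpha (TNF) at 1 ng/ml, or both agonists together. LTBR is a receptor of the TNF receptor superfamily that drives the development of lymphoid organs. At 24 h there were 4 arrays each for the control, the antibody and TNF, numbered 0 to 3 in the labels, and 3 arrays for the combination, numbered 1 to 3. At 2 h and 6 h there was 1 array each for the control, the antibody and TNF, all numbered 0. The number of arrays per group limits the precision. Every array had a trimmed mean signal of 500.0, and the median signal ranged from 106.8 to 139.0. The series title names combined signalling through a TNF receptor and LTBR and the conversion of smooth muscle cells into lymphoid tissue organizer cells, the stromal cells that attract lymphocytes. At 24 h, log2 changes are given with the SE from limma, and signals as mean ± SD over the arrays.

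The antibody alone raised genes of NF-kB signalling and of chemokines at 24 h. Nfkb2, which encodes the precursor protein of the non-canonical NF-kB pathway, had a signal of 189.7 ± 55.8 in the controls and 957.9 ± 169 with the antibody (n = 4 each), a rise of 2.31 ± 0.24 (adjusted p = 0.0018). A second Nfkb2 probe set changed by 1.05. The chemokine genes Ccl5 and Cxcl10, whose products attract T cells, rose by 2.68 ± 0.46 and 2.45 ± 0.42 (adjusted p = 0.0433 for each). Birc3 and Birc2, which encode inhibitors of apoptosis that also act in the NF-kB pathway, rose by 1.20 ± 0.20 and 1.04 ± 0.18, and the NF-kB inhibitor gene Nfkbia by 0.97 ± 0.13 (adjusted p = 0.00886), where its 4 other probe sets changed by 0.64 to 1.74. Rrad, a small GTPase gene, rose by 2.65 ± 0.47, Casp4, an inflammatory caspase gene, 2.59-fold, and the MHC class I gene H2-K1 by 0.94 (0.45 to 1.84 on 3 other probe sets). Prrg1 rose by 0.89 ± 0.12, although a second Prrg1 probe set changed by -0.06. Each of these 10 genes was higher with the antibody in 4 of 4 arrays compared with the control array of the same number, which the rule for named genes requires.

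With the antibody, 16 of 12446 genes rose and 0 fell, and 536 had an unadjusted limma p under 0.05. With the replicate number as a block, 595 genes were called, 318 higher and 277 lower, and this split became 411 higher and 61 lower after scaling the arrays to equal medians. Of 15 arrays left out in turn, 12 ended the call of Ccl5, 13 those of Cxcl10 and of Rrad, 11 that of Birc2 and 10 that of Birc3. These losses are of the fit without the block. With all arrays, the 16 genes were also called with the block. Of the gene lists, the inflammatory chemokines (2 of 12 members rose, 6 when adjusted over the list alone, median 0.95, adjusted p = 1.76e-11) were higher than the other genes. The NF-kB feedback and target genes were higher too (3 of 22 rose, 11 rose and 1 fell over the list alone, median 0.46, adjusted p = 1.31e-15), as were the MHC class I antigen presentation genes (1 of 16 rose, 9 over the list alone, median 0.36, adjusted p = 1.55e-14). The NF-kB subunits and kinase regulators (3 of 13, 4 over the list alone, median 0.13, adjusted p = 2e-09) and the lymphoid tissue organizer genes (1 of 12, 3 over the list alone, median 0.24, adjusted p = 4.7e-05) were higher as well. The called organizer gene, Nfkb2, is also counted among the NF-kB subunits. With the block and an estimated correlation, the MHC class I and organizer calls were lost (adjusted p = 0.101 and 0.0668). The interferon-stimulated genes were higher as a list (median 0.34, 0 of 33 called and 0 over the list alone, adjusted p = 2.29e-07), but not with an estimated correlation (adjusted p = 0.478). The smooth muscle contractile genes (median -0.15, 0 of 24 called) and the adipocyte markers (median -0.28, 0 of 5 called) were lower as lists, with adjusted p = 0.0033 and 0.0448, and adjusted p = 0.505 and 0.135 with an estimated correlation. Only with the block were the complement and acute phase genes (median 0.26, adjusted p = 0.0666 and 0.000184 with the block) and the cell cycle genes (median 0.10, adjusted p = 0.056 and 0.00122 with the block) called, and with the block and an estimated correlation they had adjusted p = 0.0951 and 0.578. Members that rose with the block were 7 chemokines, 13 NF-kB feedback and target genes (1 fell), 6 MHC class I genes, 5 NF-kB subunits and 4 organizer genes. Also higher were 2 interferon-stimulated, 2 complement and acute phase and 2 cell cycle genes. With it 7 contractile genes and 1 adipocyte marker fell, and 1 contractile gene rose.

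TNF alone raised chemokine, acute phase, interferon-inducible and antigen presentation genes. Ccl5 rose from 32.5 ± 38.3 to 1257 ± 407, a change of 5.16 ± 0.46 (adjusted p = 9.87e-05), and the monocyte chemokine genes Ccl7 and Ccl2 rose by 4.38 ± 0.50 and 16-fold (adjusted p = 0.00073 and 0.00282). Hp, which encodes the acute phase protein haptoglobin, rose from 101.9 ± 94.1 to 1278 ± 423 (adjusted p = 0.00107). The interferon-inducible genes Gbp2 and Oasl2 rose by 2.58 ± 0.36 and 2.55 ± 0.45, and Psmb8 and Psmb9, subunits of the immunoproteasome that prepares peptides for MHC class I, by 2.29 ± 0.29 and 2.26 ± 0.36. Tnfrsf9, a receptor gene of the TNF receptor superfamily, rose by 2.40 ± 0.27 and Bcl3, an atypical NF-kB inhibitor family member, by 2.24 ± 0.41. These 10 genes were higher in 4 of 4 arrays compared with the control of the same number, which the rule for named genes requires.

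With TNF, 42 of 12446 genes rose and 0 fell, with 583 at an unadjusted limma p under 0.05. The block gave 738 calls, 380 higher and 358 lower, or 344 higher and 140 lower after scaling to equal medians. Of 15 arrays left out in turn, 10 ended the call of Bcl3, 6 that of Oasl2 and 4 that of Psmb9, in the fit without the block. With all arrays, the 42 genes were also called with the block. Of the lists, the interferon-stimulated genes (4 of 33 rose, 24 over the list alone, median 1.03, adjusted p = 8.44e-43) were higher. So were the MHC class I genes (9 of 16, 13 over the list alone, median 0.65, adjusted p = 6.15e-38) and the NF-kB feedback and target genes (6 of 22, 16 over the list alone, median 0.60, adjusted p = 1.93e-31). The same held for the chemokines (3 of 12, 6 over the list alone, median 0.71, adjusted p = 2.17e-15) and the complement and acute phase genes (1 of 17, 7 over the list alone, median 0.75, adjusted p = 2.69e-11). Further lists with higher members were the organizer genes (2 of 12, 3 over the list alone, median 0.49, adjusted p = 6.3e-07) and the NF-kB subunits (2 of 13, 4 over the list alone, median 0.07, adjusted p = 3e-06). Nfkb2 is counted in both of these lists. With the block and an estimated correlation, the calls of the interferon genes and NF-kB subunits were lost (adjusted p = 0.111 and 0.0974). The TNF superfamily list was called higher (1 of 16 rose, mean 0.19, adjusted p = 0.039) although its median was -0.01, and lost the call with an estimated correlation (adjusted p = 0.351) and with the block (adjusted p = 0.0966). Cell cycle genes (median -0.28, 0 of 38 called) and contractile genes (median -0.19, 0 of 24 called) were lower as lists, with adjusted p = 0.000871 and 0.0033, and adjusted p = 0.703 and 0.505 with an estimated correlation. The adipocyte markers (median -0.34, 0 of 5 called) had adjusted p = 0.095, and 0.0291 with the block (adjusted p = 0.301 with the block and an estimated correlation). Members that rose with the block were 25 interferon-stimulated genes, 16 NF-kB feedback and target genes, 7 chemokines, 9 complement and acute phase genes, 5 organizer genes, 5 NF-kB subunits and 2 of the TNF superfamily. With the block 12 contractile genes fell and 1 rose, and 6 cell cycle genes and 1 adipocyte marker fell.

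The combination gave the most called genes of the comparisons with the control. Ccl5 rose from 32.5 ± 38.3 (n = 4) to 5235 ± 974 (n = 3), a change of 7.26 ± 0.50 (adjusted p = 4.81e-06), which was 6.38 to 7.93 over the other settings. The mean control signals of Ccl5, Ccl7 (30.8) and Rrad (26.6) lie under 36, the 25th percentile of the signals at 24 h. Ccl7, Ccl2 and Cxcl10 rose by 5.93 ± 0.54, 5.23 ± 0.59 and 4.87 ± 0.46. Oasl2, Gbp2 and the nucleic acid sensor gene Zbp1 rose by 4.03 ± 0.49, 3.57 ± 0.39 and 3.50 ± 0.62, Hp by 3.77 ± 0.49, Psmb9 by 3.70 ± 0.39 and the NF-kB inhibitor gene Nfkbie by 3.69 ± 0.44 (2.58 on a second probe set). The largest falls by the same rule were those of Acta1, the skeletal muscle actin gene, by 1.76 on the log2 scale (464 ± 193 to 122.6 ± 19.5, adjusted p = 0.013). They were followed by the transcription factor gene Atoh8 (-1.39 ± 0.27), Gramd1c (-1.38 ± 0.27), the lipoprotein lipase gene Lpl (-1.30 ± 0.28) and Id4, which encodes an inhibitor of basic helix-loop-helix factors (-1.24 ± 0.24). All of these genes moved the same way in 3 of 3 arrays compared with the control of the same number, which the rule for named genes requires.

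**Figure D1:**
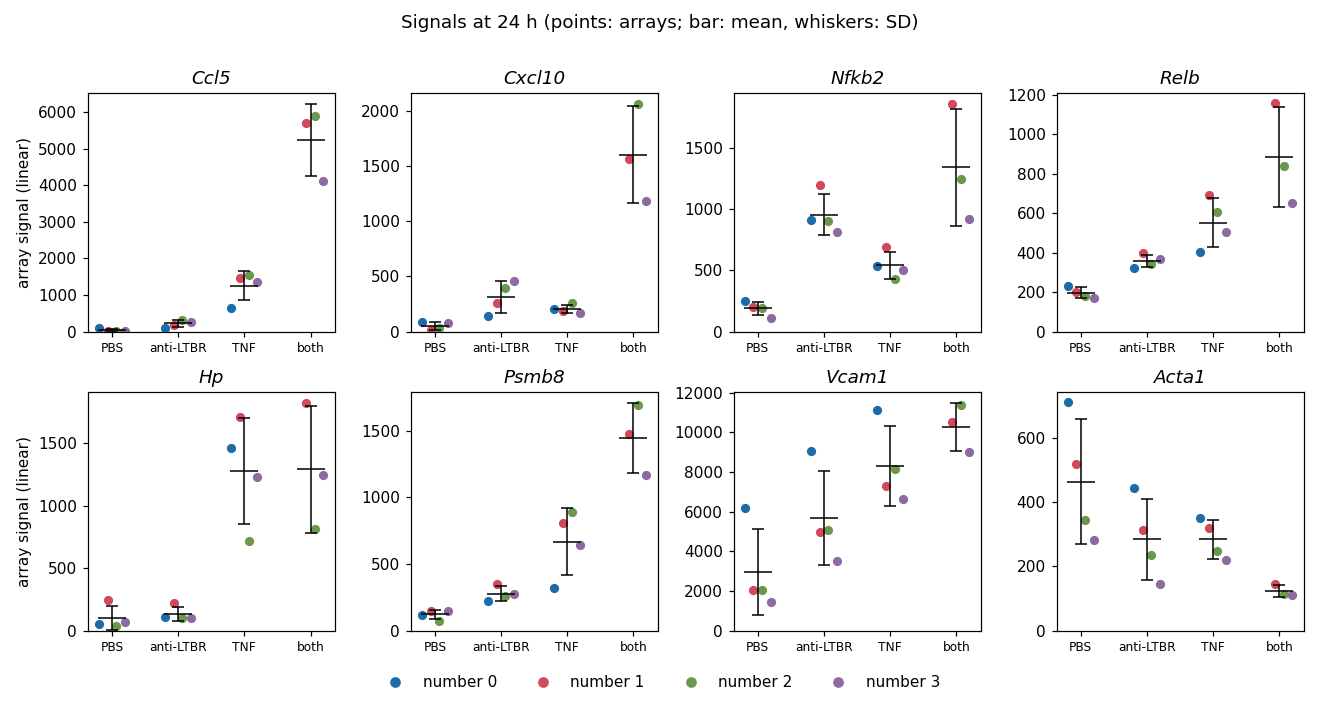
Array signals (linear scale) of 8 genes at 24 h with PBS, the antibody to LTBR, TNF and both agonists, with 1 point per array coloured by its number, and the mean with whiskers of 1 SD. For Ccl5 the 3 arrays with both agonists lie between 4115 and 5885 and the TNF arrays between 656 and 1535.

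With both agonists 226 of 12446 genes rose and 79 fell, 126 and 16 of them at least 2-fold, and 1427 had an unadjusted limma p under 0.05. The block gave 2422 calls, 1132 higher and 1290 lower, or 924 higher and 860 lower after scaling to equal medians. Without the block the calls became 182, 151 higher and 31 lower, after scaling the arrays to equal medians. Of the genes named for this comparison, the call of Tagln was ended by 13 of 15 arrays left out in turn, that of Chac1 by 11, that of Lpl by 5, that of Tnfrsf1b by 4 and that of Saa3 by 3. The calls of Vcam1, Acta1, Gramd1c, Lcn2 and Traf2 were ended by 2 each, and those of Atoh8, Id4, Cfb and Myc by 1 each. These losses are of the fit without the block. With all arrays, the 305 genes called in that fit were also called with the block.

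Of the lymphoid tissue organizer genes, 3 of 12 tested members rose with both agonists, 5 when adjusted over the list alone and 7 with the block (median 0.97, adjusted p = 7.49e-06). Ccl19, Ccl21a, Madcam1 and Tnfsf11 were also on the list but were not among the tested genes, so nothing follows for them. Nfkb2 rose by 2.75 ± 0.26 (1.32 on a second probe set), its partner gene Relb by 2.09 ± 0.20 (adjusted p = 3.61e-05 for each) and Vcam1, an adhesion molecule for lymphocytes, by 2.03 ± 0.40 (2943 ± 2178 to 10280 ± 1207, adjusted p = 0.013). Of these, Nfkb2 and Relb are also counted among the NF-kB subunits. The adhesion molecule gene Icam1 (2.58 ± 0.76, adjusted p = 0.114), the lymphocyte survival factor gene Il7 (0.94 ± 0.34, adjusted p = 0.235), Bst1 (1.12 ± 0.54, adjusted p = 0.462) and the B cell chemokine gene Cxcl13 (0.99 ± 0.86, adjusted p = 0.791) were called with the block. Their changes with the block were 3.13, 0.70, 0.70 and 1.65 (adjusted p = 5.35e-06, 0.00429, 0.00186 and 1.81e-05). On the numbers 1 to 3 Icam1, Il7 and Cxcl13 were also called without the block (adjusted p = 0.00024, 0.022 and 0.0319), as was Icam1 without the control array numbered 0 (adjusted p = 0.0051). Cxcl13 signals on the arrays numbered 1, 2 and 3 were 109.5, 127.1 and 264.6 in the controls and 405.5, 660.0 and 509.1 with both agonists, while the control array numbered 0 had 1057. Pdpn (0.26 ± 0.32), Tnfrsf11b (-0.11 ± 0.22), Tnfsf13b (0.09 ± 0.25), Cxcl12 (-0.04 ± 0.09) and Ltbr itself (0.02 ± 0.11) were called neither way. The endothelial markers, of which 0 of 18 were called, had a median of -0.70 in this comparison (adjusted p = 0.0579) and -0.02 with the block. Pecam1, the endothelial adhesion molecule, had a mean signal of 5237 on the 24 h arrays numbered 0, a number that the combination lacks, and 188.2 on those numbered 1 to 3.

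Genes of inflammation and antigen presentation rose in most of the lists fixed for them. Of the inflammatory chemokines 7 of 12 rose (8 rose and 1 fell over the list alone, median 1.94, adjusted p = 1.55e-14), and of the NF-kB feedback and target genes 13 of 22 (17 rose and 1 fell over the list alone, median 0.88, adjusted p = 1.88e-21). Among the latter, Birc3 rose 5.38-fold, the receptor gene Tlr2 4.47-fold, Tnip1 2.22-fold and the transcription factor gene Irf1 2.15-fold. Of the NF-kB subunits and kinase regulators 4 of 13 rose (7 over the list alone, 7 with the block, median 0.36, adjusted p = 7.39e-08), with Birc2 at 1.46 ± 0.20 and Traf2, an adaptor of TNF receptors, at 0.70 ± 0.13. Of the MHC class I genes 12 of 16 rose (13 over the list alone, median 1.24, adjusted p = 5.99e-31), with Psmb8 11.1-fold, Psmb10 6.66-fold and the peptide loading gene Tapbp 2.85-fold higher, and H2-K1 higher by 2.13 (1.75 to 4.17 on 3 other probe sets). Probe sets of H2-K1 may cross-hybridise with other class I genes. Of the interferon-stimulated genes 22 of 33 rose (31 over the list alone, median 1.85, adjusted p = 1.77e-41), with Gbp3 at 3.48 ± 0.42 and Bst2, a restriction factor gene, at 2.31 ± 0.26. Members of the Gbp family are similar in sequence and may cross-hybridise. The interferon list was also called with an estimated correlation (adjusted p = 0.0355), but neither it nor the NF-kB subunits with the block and an estimated correlation (adjusted p = 0.14 and 0.0668). Of the TNF superfamily ligands and receptors 2 of 16 rose (4 over the list alone), Tnfrsf9 by 3.31 ± 0.30 and Tnfrsf1b by 1.07 ± 0.23 (0.70 on a second probe set). The list call (median 0.08, adjusted p = 0.0335) was lost with an estimated correlation (adjusted p = 0.341) and with the block (adjusted p = 0.119). Fas (0.73 ± 0.22) and Tnfrsf10b (0.47 ± 0.14) passed with the block (adjusted p = 0.00127 and 0.0418), where 4 members rose. Tnfrsf10b also passed without the variance trend (adjusted p = 0.0403). Of the MHC class II genes Cd74, the invariant chain gene, rose by 1.45 ± 0.20, while H2-DMa, H2-Eb1 and Ciita, the class II transactivator gene, were not called (1 of 6 rose, median 0.17, adjusted p = 0.0806). Of the complement and acute phase genes 5 of 17 rose (8 over the list alone, 12 with the block), including Lcn2 (lipocalin), Saa3 (serum amyloid) and Cfb (complement factor B) by 3.29 ± 0.67, 3.16 ± 0.67 and 2.26 ± 0.45. The list call (median 0.97, adjusted p = 3.12e-08) was lost with an estimated correlation (adjusted p = 0.0875), but not with the block added to it (adjusted p = 0.019).

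**Figure D2:**
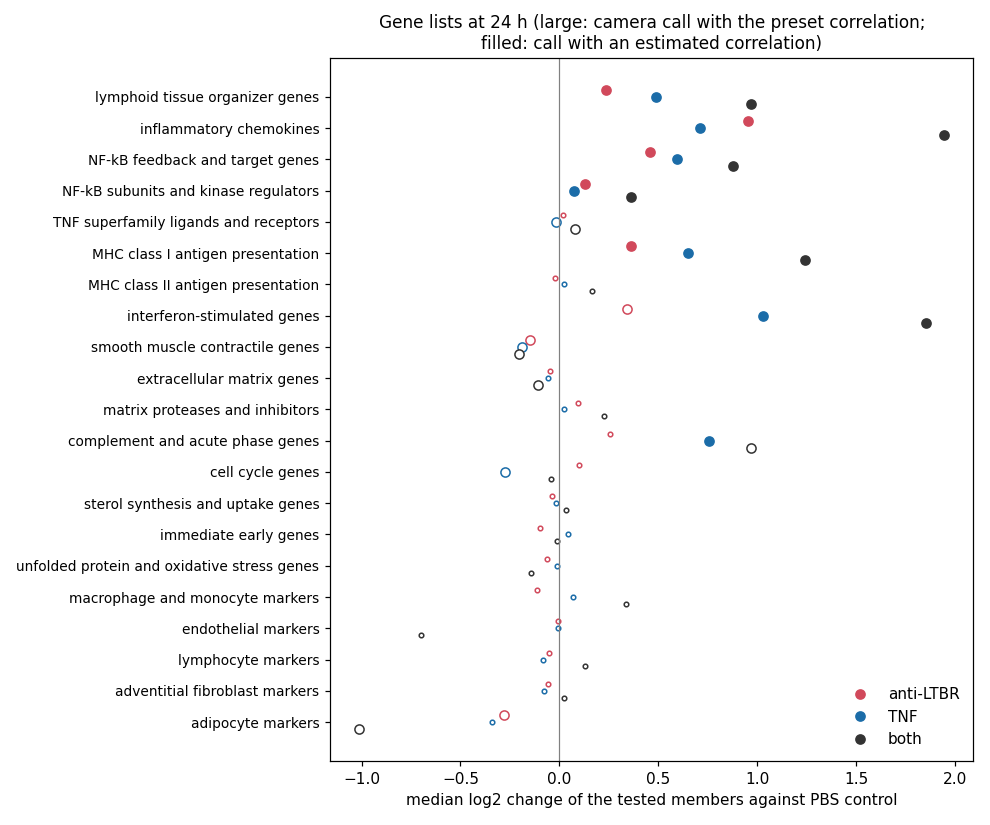
Median log2 change of the tested members of 21 gene lists at 24 h against the PBS control, for the antibody, TNF and both agonists. Large symbols mark a camera call with the preset correlation and filled symbols a call with an estimated correlation, and the median of the interferon-stimulated genes is 0.34, 1.03 and 1.85.

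Of the smooth muscle contractile genes 2 of 24 fell with both agonists (3 over the list alone), Vcl (vinculin) by 0.48 and Tagln (transgelin) by 0.30 on the log2 scale, and 15 fell and 1 rose with the block. Tpm2 (tropomyosin, -0.39 ± 0.10, adjusted p = 0.052) and Cnn1 (calponin, -0.98 ± 0.32, adjusted p = 0.177) passed with the block (adjusted p = 1.85e-06 and 4.47e-05). Without it Tpm2 also passed after quantile normalization (adjusted p = 0.0176), on the numbers 1 to 3 (adjusted p = 0.00859) and without 5 of 15 arrays left out in turn. The list was lower (median -0.21, adjusted p = 0.000207) but not with an estimated correlation (adjusted p = 0.374). The extracellular matrix genes were lower as a list (median -0.11, adjusted p = 0.00322, adjusted p = 0.306 with an estimated correlation), with 0 of 34 called, 0 over the list alone, and 14 lower and 2 higher with the block. The proteoglycan gene Vcan changed by -0.91 ± 0.26, Col8a1 by -0.34 ± 0.10, Col3a1 by -0.22 ± 0.09 and the elastin gene Eln by -0.18 ± 0.06, each called with the block. Of the matrix proteases and inhibitors 0 of 20 were called, 1 rose over the list alone, and 9 rose and 2 fell with the block (median 0.23, adjusted p = 0.0555). Called with the block were the inhibitor gene Timp1 (0.46 ± 0.12) and the protease genes Mmp9 (1.36 ± 0.45), Adamts4 (0.67 ± 0.21) and Mmp14 (0.31 ± 0.17). Of the stress genes 2 of 25 rose and 2 fell, and 5 rose and 7 fell with the block. The metallothionein genes Mt2 and Mt1 rose by 2.35 ± 0.31 and 1.59 ± 0.24. Atf4, the transcription factor gene of the integrated stress response, and its target Chac1 fell by 0.50 and 0.88 (list median -0.14, adjusted p = 0.262). Of the immediate early genes 2 of 25 rose, Junb by 1.41 ± 0.20 and Myc by 0.87 ± 0.17 (list median -0.01, adjusted p = 0.738), and 6 rose and 3 fell with the block. Fos (-1.25 ± 0.42, adjusted p = 0.193) and Fosl1 (0.78 ± 0.25, adjusted p = 0.143) were called only with the block (adjusted p = 1.78e-05 and 0.000685).

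Of the cell cycle genes 0 of 38 were called with both agonists (median -0.04, adjusted p = 0.933), and with the block 8 rose and the list was higher (median 0.16, adjusted p = 0.00303, adjusted p = 0.614 with the block and an estimated correlation). Ccne1 (cyclin E, 0.56 ± 0.17) and Mcm7 (a replication helicase subunit, 0.42 ± 0.27) were among those called with the block, and Cenpa (-0.51 ± 0.40) and E2f1 (-0.30 ± 0.26) were not. Of the sterol synthesis and uptake genes 0 of 20 were called (median 0.03, adjusted p = 0.654), and 2 rose and 2 fell with the block, with Pmvk at -0.56 ± 0.21 (adjusted p = 0.0203 with the block), Mvk at 0.39 ± 0.22, Dhcr7 at 0.21 ± 0.13 and Ebp at 0.20 ± 0.11. Among markers of other cell types, 1 of 5 adipocyte markers fell, Lpl, which other cells also express, and 3 fell with the block. The list call (median -1.01, adjusted p = 0.0206) was lost with an estimated correlation (adjusted p = 0.083). Pparg (-1.17 ± 0.69) and Cebpa (-1.01 ± 0.38) were called with the block only, and Fabp4 (-0.41 ± 0.39) was not called. Of the endothelial markers Erg (-0.95 ± 0.40, adjusted p = 0.354) was called with the block only (adjusted p = 0.000531), and Tek (-0.95 ± 0.55), Flt1 (-1.01 ± 0.62) and Egfl7 (-0.90 ± 0.72) were not. The macrophage and monocyte markers (0 of 15 called, median 0.34, adjusted p = 0.339), with Fcer1g at 0.78 ± 0.58, Cd14 at 0.60 ± 0.37, Cd53 at 0.45 ± 0.35 and C1qc at -1.13 ± 1.19, were not called as a list. Neither were the lymphocyte markers (0 of 5, median 0.13, adjusted p = 0.706), with Zap70 at 0.53 ± 0.48, Pax5 at 0.18 ± 0.20, Cd22 at -0.43 ± 0.46 and Cd8a at 0.13 ± 0.28. The adventitial fibroblast markers were not called either (0 of 13, median 0.02, adjusted p = 0.615), with Dpt at 1.67 ± 0.71, Pdgfra at 0.64 ± 0.19, Dpep1 at 0.36 ± 0.32 and Serpinf1 at -0.50 ± 0.66. C1qc was lower (adjusted p = 0.036), and Pdgfra and Dpt were higher (adjusted p = 0.000278 and 0.0363), with the block, where 4 fibroblast markers were lower.

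**Figure D3:**
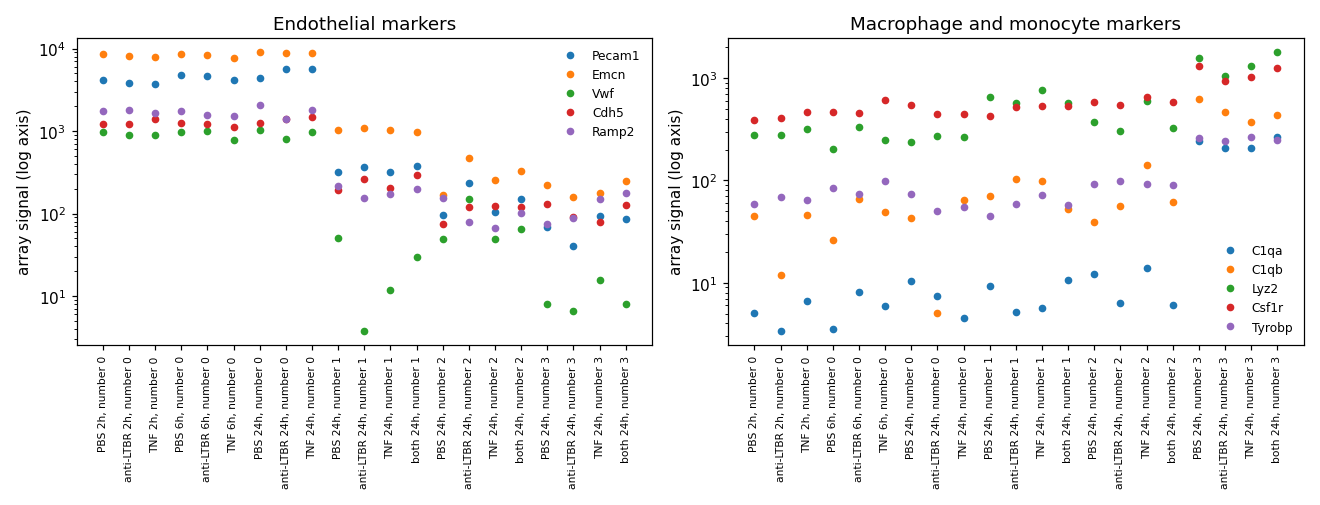
Array signals (log axis) of 5 endothelial and 5 macrophage and monocyte markers on all 21 arrays, ordered by number, time and treatment. The arrays numbered 0 have Pecam1 signals far above the others (mean 5237 at 24 h), and the arrays numbered 3 have C1qa signals (mean 231.8) above the others.

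The comparison of the combination with TNF alone asks what the antibody added. Cxcl10 was 7.48-fold higher with both agonists than with TNF (1607 ± 439, n = 3, and 203.4 ± 39.8, n = 4; 2.90 ± 0.46, adjusted p = 0.0456). The chemokine gene Ccl9 rose by 1.68 ± 0.26, Birc3 by 1.35 ± 0.22, the vesicle fusion gene Stx11 by 1.28 ± 0.16 (adjusted p = 0.0139) and Zfp36l1, an RNA-binding protein gene, by 0.84 ± 0.13. These genes and 2210408K08Rik (0.72 ± 0.11), which is outside the rule for named genes, were the 6 called genes, all higher, with 591 at an unadjusted p under 0.05. With the block 844 genes were called, 431 higher and 413 lower, and 494 after scaling to equal medians, 243 higher and 251 lower. Of 15 arrays left out in turn, 13 ended the calls of Ccl9, Birc3 and Zfp36l1, 12 that of Cxcl10 and 6 that of Stx11, without the block. With all arrays, the 6 genes were also called with the block. Of the lists, the MHC class I genes (0 of 16 called, 9 rose over the list alone, median 0.44, adjusted p = 3.29e-14) were higher. So were the chemokines (2 of 12, 5 over the list alone, median 0.86, adjusted p = 4.87e-08) and the NF-kB subunits (0 of 13, 3 over the list alone, median 0.19, adjusted p = 1.29e-05). With the block and an estimated correlation, the MHC class I and NF-kB subunit calls were lost (adjusted p = 0.14 and 0.105). The interferon-stimulated genes (0 of 33, 1 over the list alone, median 0.80, adjusted p = 3.92e-17) were higher too, but not with an estimated correlation (adjusted p = 0.212). Their mean log2 signal with TNF was lowest on number 0 (8.671), a number that the combination lacks. On the numbers 1, 2 and 3 it was 9.628, 10.138 and 9.829 with TNF and 10.188, 10.73 and 10.214 with both agonists. The NF-kB feedback and target genes (1 of 22, 8 rose and 1 fell over the list alone, median 0.28, adjusted p = 4.52e-06) had adjusted p = 0.0631 with an estimated correlation. The organizer genes (0 of 12, 2 over the list alone, median 0.39, adjusted p = 0.0137) and the cell cycle genes (0 of 38, median 0.23, adjusted p = 0.00484) were also higher, with adjusted p = 0.0598 and 0.756 with an estimated correlation. With the block, 18 cell cycle genes rose (median 0.45). So did 9 MHC class I genes, 8 chemokines, 8 NF-kB feedback and target genes (1 fell), 5 NF-kB subunits, 5 organizer genes and 4 interferon-stimulated genes. With it 7 contractile genes, 4 extracellular matrix genes and 1 adipocyte marker fell. The contractile genes (median -0.08, mean 0.01) and the extracellular matrix genes (median -0.07) were lower with adjusted p = 0.00975 and 0.00145, and adjusted p = 0.573 and 0.282 with an estimated correlation. After quantile normalization both calls were lost (adjusted p = 0.249 and 0.324). The endothelial markers were lower (median -0.60, adjusted p = 0.022, adjusted p = 0.682 with an estimated correlation) but not with the block (median 0.05, adjusted p = 0.96). The complement and acute phase genes (median 0.27, adjusted p = 0.139) and the adipocyte markers (median -0.41, adjusted p = 0.0806) were called with the block only (adjusted p = 0.0254 and 0.033), with adjusted p = 0.262 and 0.301 with the block and an estimated correlation.

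The comparison of the combination with the antibody alone asks what TNF added, and chemokine, acute phase and interferon-inducible genes were higher. Ccl5 rose by 4.58 ± 0.50 (222.3 ± 93.8, n = 4, to 5235 ± 974, n = 3, adjusted p = 0.00268), Saa3 by 3.47 ± 0.67, Hp by 3.19 ± 0.49, Ccl7 by 3.16 ± 0.54 and Oasl2 by 2.83 ± 0.49. In all, 45 of 12446 genes rose and 0 fell, with 572 at an unadjusted limma p under 0.05. The block gave 694 calls, 345 higher and 349 lower, or 200 higher and 345 lower after scaling to equal medians. Of 15 arrays left out in turn, 10 ended the call of Saa3, 6 that of Oasl2, 4 that of Ccl7 and 1 that of Hp, without the block. With all arrays, the 45 genes were also called with the block. The interferon-stimulated genes (8 of 33 rose, 30 over the list alone, median 1.65, adjusted p = 1.63e-51) and the MHC class I genes (9 of 16, 13 over the list alone, median 0.96, adjusted p = 5.24e-36) were higher. Also higher were the NF-kB feedback and target genes (4 of 22, 10 over the list alone, median 0.53, adjusted p = 1.58e-16), the chemokines (3 of 12, 6 over the list alone, median 0.91, adjusted p = 4.1e-13) and the organizer genes (1 of 12, 1 over the list alone, median 0.54, adjusted p = 0.00145). With the block and an estimated correlation, the interferon and organizer calls were lost (adjusted p = 0.105 and 0.0668). The complement and acute phase genes were higher (2 of 17, 7 over the list alone, median 0.80, adjusted p = 3.03e-09), but not with an estimated correlation (adjusted p = 0.0676, and adjusted p = 0.0179 with the block added to it). The NF-kB subunits (1 of 13, median 0.16, adjusted p = 0.00835) and the TNF superfamily (1 of 16, median 0.15, adjusted p = 0.0172) had adjusted p = 0.15 and 0.292 with an estimated correlation. The block ended the call of the TNF superfamily (adjusted p = 0.0532). The contractile genes (median -0.06, mean 0.01, adjusted p = 0.00944), the extracellular matrix genes (median -0.10, adjusted p = 0.00278) and the endothelial markers (median -0.65, adjusted p = 0.0106) were lower as lists, with adjusted p = 0.573, 0.305 and 0.638 with an estimated correlation. The endothelial median was 0.03 with the block (adjusted p = 0.664), and after quantile normalization the contractile and matrix calls were lost (adjusted p = 0.0839 and 0.0909). The adipocyte markers (median -0.59, adjusted p = 0.137) were called lower with the block only (adjusted p = 0.0386, and adjusted p = 0.315 with the block and an estimated correlation). In the lists named here, members that rose with the block included 28 interferon-stimulated genes, 12 NF-kB feedback and target genes, 9 chemokines, 9 complement and acute phase genes, 4 organizer genes, 3 NF-kB subunits and 2 of the TNF superfamily. With it 7 contractile genes, 4 extracellular matrix genes, 1 endothelial marker and 1 adipocyte marker fell.

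Between the single agonists, Hp and H2-K1 were higher with TNF than with the antibody. Hp had a signal of 1278 ± 423 with TNF and 132.7 ± 59.3 with the antibody (n = 4 each), a difference of 3.18 ± 0.45. H2-K1 differed by 0.89 ± 0.13 (adjusted p = 0.0367 for each gene). Both were higher in 4 of 4 arrays of the same number, which the rule for named genes requires. These were the 2 calls, with 241 at an unadjusted p under 0.05, and the block gave 90, 43 higher and 47 lower, or 32 higher and 61 lower after scaling to equal medians. Of 15 arrays left out in turn, 12 ended the call of Hp and 11 that of H2-K1, in the fit without the block. With all arrays, these 2 genes were also called with the block. Nfkb2 was lower with TNF than with the antibody when the block was used (-0.82 ± 0.24, adjusted p = 1, and 0.0172 with the block). The MHC class I genes (1 of 16 called, 6 over the list alone, median 0.39, adjusted p = 3.9e-24) were higher with TNF. So were the NF-kB feedback and target genes (0 of 22, 5 over the list alone, median 0.18, adjusted p = 9.24e-08) and the chemokines (0 of 12, 3 higher and 1 lower over the list alone, median 0.22, adjusted p = 0.00355). Both calls were lost with the block and an estimated correlation (adjusted p = 0.1 and 0.193). The interferon-stimulated genes (0 of 33, 7 over the list alone, median 0.73, adjusted p = 5.32e-34) and the complement and acute phase genes (1 of 17, 5 over the list alone, median 0.43, adjusted p = 4.68e-10) were higher too, with adjusted p = 0.0578 and 0.0579 with an estimated correlation, and adjusted p = 0.14 and 0.0179 with the block added to it. The cell cycle genes were lower with TNF than with the antibody (0 of 38 called and 0 over the list alone, median -0.41, adjusted p = 4.26e-12), but not with an estimated correlation (adjusted p = 0.344). The macrophage and monocyte markers (median 0.11, adjusted p = 0.184) were called with the block only (adjusted p = 0.0232, and adjusted p = 0.342 with the block and an estimated correlation). With the block 8 complement and acute phase genes, 7 MHC class I genes, 5 interferon-stimulated genes, 4 NF-kB feedback and target genes and 4 chemokines were higher with TNF. In that fit 5 cell cycle genes and 1 chemokine were lower.

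The interaction asks whether the change with both agonists differed from the sum of the single changes on the log2 scale. Of 12446 genes 0 were called by limma, with 165 at an unadjusted p under 0.05, and 2 were called with the block, both with a smaller combined change than the sum. In that fit Clca3a2, a calcium-activated chloride channel family gene, changed by 2.55 with the antibody, 2.26 with TNF and 2.89 with both (interaction -1.92 ± 0.20 and adjusted p = 0.00293 with the block). Nfkbia changed by 0.97, 1.02 and 1.22 (interaction -0.77 ± 0.09 and adjusted p = 0.00744 with the block). Of 4 further Nfkbia probe sets, 3 had interactions of -0.84 to -1.02 with the block and the one of lowest signal had -0.00. As lists, the interferon-stimulated genes had a positive interaction (median 0.40, adjusted p = 0.000371, adjusted p = 0.638 with an estimated correlation), which was 0.05 over the arrays numbered 1 to 3 (adjusted p = 0.5). The NF-kB feedback and target genes had a negative one (median -0.09, 0 of 22 called, 1 lower over the list alone, adjusted p = 0.00771, adjusted p = 0.292 with an estimated correlation). The endothelial markers had a median interaction of -0.38 (adjusted p = 0.0484, adjusted p = 0.726 with an estimated correlation) and 0.02 with the block (adjusted p = 0.897). The cell cycle genes (median 0.40, adjusted p = 1.22e-11) and the extracellular matrix genes (median -0.04, adjusted p = 0.00813) were called with the block only, with adjusted p = 0.399 and 0.061 without it, and adjusted p = 0.268 and 0.547 with the block and an estimated correlation.

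The single agonists shared part of their calls. Of the 42 genes that rose with TNF and the 16 that rose with the antibody, 9 rose with both treatments, among them Nfkb2, Nfkbia, Birc3, Ccl5, Irf1 and H2-K1. Independent lists of these sizes would share 0.05, and 20 simulations of unchanged groups against the same controls had 0 calls, so that they give no shared count to compare with. With the block 169 genes rose and 171 fell in both comparisons, where independent lists would share 9.71 and 7.97. Because the control arrays are the same, the controls were also divided into pairs in all 6 ways, but the antibody then had 0 calls, so that shared calls could not be counted. Across genes, which are not independent replicates, the fold changes correlated at 0.675 against 0.504 in the simulations, with a covariance of 0.0387 against 0.0114, a difference of 0.0273. With divided controls the covariance was 0.001, and 0.0264 where each control array was set against treated arrays of its own number.

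At 2 h and 6 h each treatment had 1 array, so the differences have no replicate check and no test. At 2 h with TNF, 157 genes were at least 2-fold higher and 60 lower than on the control array, led by Ccl7 (4.64) and Ccl2 (4.05, signals of 9566 and 568.0). Next came Nfkbie (3.85), the sulfotransferase gene Chst15 (3.72) and Sele, which encodes the endothelial adhesion molecule E-selectin (3.59, signals of 9763 and 799.0). All arrays at 2 h and 6 h are numbered 0 and had a mean signal of 4217 for the endothelial marker Pecam1. On the 24 h arrays numbered 1 to 3 that mean was 188.2. Which cells the differences at 2 h and 6 h came from was not tested. At 6 h with TNF the numbers were 224 and 50, led by Ccl7 (4.88), Ccl5 (4.06), Ccl2 (3.89), Cxcl10 (3.50) and Gbp2 (3.21). With the antibody 45 genes were higher and 39 lower at 2 h, and 79 and 30 at 6 h. The largest of these differences came from low signals: 4931413K12Rik, Rimklb, Slc34a3, Gh and Tmem191c at 2 h and Kcna7, Lgr5, Muc3, BE949265 and Chst15 at 6 h had control signals between 10.6 and 38.3. The largest decreases were those of Trim43a, Ankrd9 and Cphx3 at 2 h with TNF, 2610316D01Rik, Tas2r108 and Irs4 at 2 h with the antibody, Rnf39, Rtel1 and Mfap4 at 6 h with TNF, and Zfp688, Rtel1 and Mfap4 at 6 h with the antibody. Rtel1 was -3.82 at 6 h and 3.23 at 24 h with TNF on the arrays numbered 0. Between 24 h arrays of the same group, 312 to 1035 genes were at least 2-fold apart in the 21 pairs, which also differ in number, and 93 genes between the control arrays of 2 h and 6 h.

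Along the series numbered 0, genes differed in when they were highest. Nfkb2 was 1.68, 1.73 and 1.09 above the control at 2, 6 and 24 h with TNF, and 0.37, 1.30 and 1.84 with the antibody. Birc3 had 3.08, 2.42 and 1.23 with TNF and 0.85, 1.74 and 1.43 with the antibody, and Relb 2.69, 1.90 and 0.77 with TNF and 0.70, 1.13 and 0.45 with the antibody. Hp reached 1.00, 2.86 and 4.47 with TNF. Among lists, the NF-kB feedback and target genes had a median difference of 1.00 at 2 h, 0.83 at 6 h and 0.39 at 24 h with TNF, and 0.15, 0.36 and 0.33 with the antibody. The interferon-stimulated genes had 0.43 at 2 h and 1.23 at 6 h with TNF, where 22 of 33 were at least 2-fold higher, and 0.37 at 24 h, where 4 were. With the antibody they had 0.14 at 2 h, -0.11 at 6 h and -0.04 at 24 h. In percentiles among 10000 random lists of the same size and mean expression, the medians at 2 h and 6 h stood at 100 for TNF in both lists, at 99.99 and 100 for the NF-kB genes with the antibody, and at 99.98 and 0.08 for the interferon genes with the antibody at 2 h and 6 h. The random lists were not matched on the correlation between genes. An extreme percentile on 1 pair of arrays therefore does not exclude chance. The chemokines had 1.10 and 1.29 with TNF (percentile 100 at each time) and 0.15 and 0.42 with the antibody (99.13 and 100). At 24 h they had 0.53 with TNF and 0.40 with the antibody. Over all 24 h arrays, the medians of the interferon, NF-kB feedback and chemokine lists were higher than on number 0. They were 1.03, 0.60 and 0.71 with TNF, and 0.34, 0.46 and 0.95 with the antibody. A decline by 24 h on number 0 therefore need not hold for the other numbers.

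**Figure D4:**
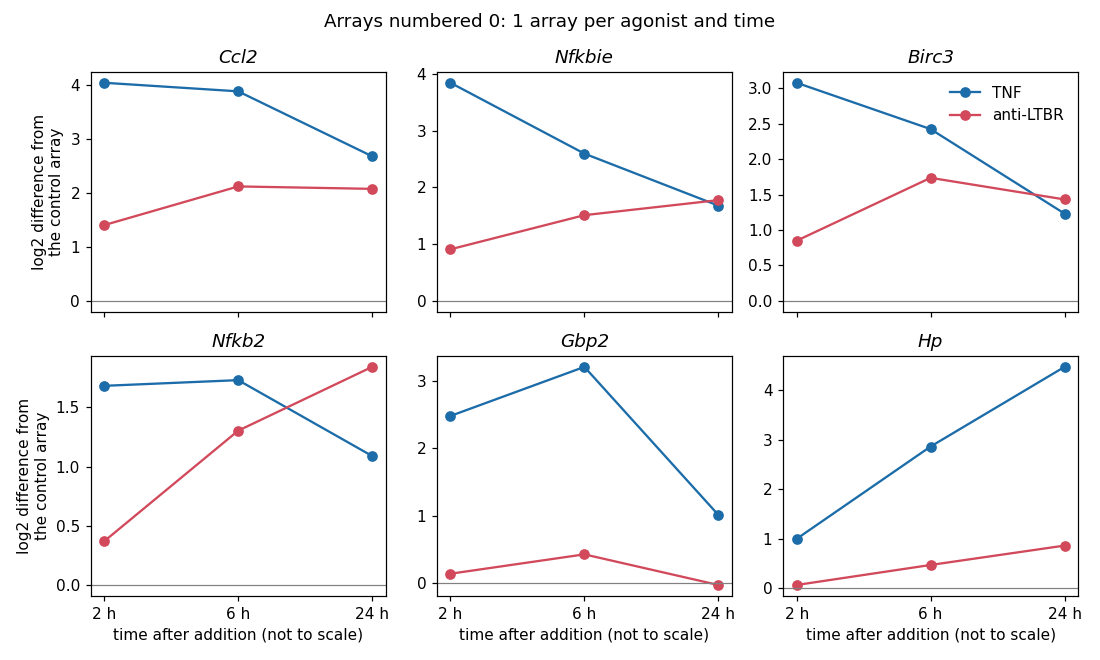
Log2 difference from the control array of the same time for 6 genes on the arrays numbered 0 at 2, 6 and 24 h (time axis not to scale), with 1 array per agonist and time. With the antibody Nfkb2 goes from 0.37 to 1.84, and with TNF Nfkbie goes from 3.85 to 1.68.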

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

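The tests of the 3 patterns weighed here and the regroupings of the interaction with the block were chosen after the results were seen, and the other counts over splits of the arrays were planned.

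The interferon-stimulated genes had a positive interaction of both agonists, with a list median of 0.40. Unequal scaling of the arrays stays open for part of it, since scaling to equal array medians took the median to 0.274, where that of all genes went from 0.03 to -0.09. A candidate explanation is the number 0, which the combination lacks: over the arrays numbered 1 to 3 the median was 0.051, against 0.516, 0.615 and 0.58 without the numbers 1, 2 and 3. Leaving out the control array numbered 3, the TNF array numbered 0 or the combination array numbered 2 also ended the call, with medians of 0.22, 0.22 and 0.30 and adjusted p = 0.0709, 0.593 and 0.161. The mean log2 signal of the list was 8.281 in the control and 8.671 with TNF on number 0. On the numbers 1, 2 and 3 it was 8.187, 8.125 and 8.944 in the controls and 9.628, 10.138 and 9.829 with TNF. The difference with TNF was thus smallest on number 0. Whether this is a different response to TNF remains open and was not tested.

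The endothelial markers had lower signals on the arrays with both agonists, with an interaction median of -0.38. A loss of smooth muscle cells from the cultures numbered 0 would raise the markers of other cell types present there. The macrophage, fibroblast, adipocyte and lymphocyte lists had medians of -0.171, -0.133, -0.108 and -0.01 on number 0 against numbers 1 and 2, as number 3 was high in macrophage markers. Their highest upper quartile was 0.17, below the lower quartile of 0.58 of the endothelial list. These lists did not rise, but some members lay near the background, such as C1qa (mean 7.4 on number 0). The contractile genes had their lowest mean log2 signal on number 0: 10.695 in the controls (10.877 to 11.596 on the others), 10.471 with the antibody (10.79 to 11.406) and 10.645 with TNF (10.803 to 11.309). Such a loss was therefore not excluded. The absence of number 0 from the combination may account for the lower endothelial signals, as the median against the control was -0.70 without and -0.017 with the block. More endothelial cells in the cultures numbered 0 are a candidate source, since 17 of 18 markers were higher on number 0 in each of 3 groups, with a median difference of 1.90, and the exception was Kdr. Signals of abundant markers on number 0 and on numbers 1 to 3 at 24 h were 8890 and 511.5 for Emcn and 934.6 and 37.2 for Vwf, and the labels describe no sort.

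The cell cycle genes were lower with TNF than with the antibody, with a list median of -0.41. That a single number carries the difference was excluded, as the median without the number 0, 1, 2 or 3 was -0.443, -0.324, -0.458 or -0.416. Unequal scaling by 1 factor per array was excluded too, as the list median at equal array medians was -0.444. The median of all genes went from -0.005 to -0.041. Such a factor moves all genes of an array about alike, so this does not exclude unequal scaling that depends on signal. Without the antibody array numbered 0 the list median was -0.19. It was -0.69, -0.22 and -0.27 without the TNF arrays numbered 0, 1 and 3. Each of these fits kept the list call with the preset correlation. A difference in proliferation between the agonists may underlie it but remains a hypothesis, since the call was lost with an estimated correlation (adjusted p = 0.344) and with fry (adjusted p = 0.578).

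Other results stood out for single arrays. Among 390 series of 4 arrays, 21 had an array far from the others, where chance at 1 in 20 gives 19.5, and 9 of them were on number 0 and 4 on each other number. Values are log2, with that of the nearest other array after them. In the controls these were, for number 0, Birc3 at 8.19 (8.7), Pmvk at 8.95 (9.22) and Tek at 8.29 (6.44). For control number 1 it was the mean of the adipocyte markers at 8.69 (8.17), and for number 2 Saa3 at 5.99 (7.12). For control number 3 they were the mean of the macrophage markers at 8.58 (6.7), Pax5 at 7.93 (7.72) and Zap70 at 10.5 (9.1). With the antibody they were Ltbr at 10.7 (10.5) for number 0, Hp at 7.85 (6.92) and the mean of the fibroblast markers at 10.3 (9.79) for number 1, Mt1 at 11.3 (12) for number 2 and C1qc at 7.79 (4.28) for number 3. With TNF they were, for number 0, Bst1 at 6.99 (8.83), Ccl5 at 9.38 (10.4), Cd14 at 7.19 (8.37), Flt1 at 9.09 (6.95) and H2-K1 at 12.8 (13.2). For TNF number 1 it was the mean of the complement and acute phase genes at 10.1 (9.16), and for number 2 the mean of the NF-kB subunits at 9.35 (9.26) and Tnfrsf1b at 7.76 (8.52).

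Further results differed between the agonist combinations in a test of the interaction. The NF-kB feedback and target genes had a list median of -0.09, and the call was lost without the control array numbered 2 (adjusted p = 0.0596), the TNF array numbered 1 (0.136) or the combination arrays numbered 2 (0.106) and 3 (0.0932). With the block the genes Clca3a2 and Nfkbia had interactions of -1.92 and -0.77, and of 4 further Nfkbia probe sets 3 had -0.84 to -1.02 and 1 had -0.00. Among 3246 probe sets without 1 gene name, which the gene tests leave out, 40 were called with both agonists, 33 higher and 7 lower, and 312 with the block, 159 higher and 153 lower.

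For each comparison of a pair of groups the arrays were split in all 35 ways, of which 1, the real one, gave as many calls, without and with the block. As the numbers pair the arrays, the real split is to be compared with the 8 splits, itself included, that part as many same-number pairs, which are too few for a share under 0.05. The real count and the highest of the other splits were 16 and 0 for the antibody, 42 and 0 for TNF, 305 and 35 for the combination, 6 and 0 against TNF, 45 and 0 against the antibody and 2 and 1 between the agonists. With the block they were 595 and 1, 738 and 0, 2422 and 1314, 844 and 55, 694 and 4, and 90 and 1. Among those 8 splits the highest other was 35 for the combination and 0 in the other comparisons, and with the block 1314 for the combination, 20 against TNF, 4 against the antibody and 0 in the other comparisons. For the interaction the real count was 0, which each of 100 random regroupings reaches whatever the data, so nothing about chance follows, and their highest of 734 points to a structure of the samples. With the block, 4 of 100 regroupings within the numbers, the real one included, gave at least the real count of 2, with a highest of 360. The regroupings keep the treatment effects in the data, so they do not stand for arrays without an interaction. Chance was therefore not excluded, and 1 more regrouping would have reached a share of 0.05. The highest again points to a structure of the samples, which includes the treatments.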

How the results depend on the processing

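The numbers 1 to 3 with the block, the shared calls with the block, the controls matched by number, and the block without each array or with another scaling were tried after the data were seen; the other alternatives were planned, and each was run. Unless a construction is named, the cause was not tested. Counts are given in the order antibody, TNF, combination (each against the control), combination against TNF, combination against the antibody, and TNF against the antibody, and those not given stayed within 1.5 times. With the block they were 595, 738, 2422, 844, 694 and 90, with 2 for the interaction, and on the numbers 1 to 3 with the block 314, 569, 2163, 610, 506 and 80, with 11 for the interaction. With only the groups compared, a fit with fewer arrays, they were 1, 15, 190, 1, 18 and 1. Scaling to equal medians gave 7 for the antibody, 182 for the combination, 0 against TNF, 25 against the antibody and 0 between the agonists. Without a pseudocount there were 3 against TNF and 0 between the agonists, without a filter 8 for the antibody and 1 against TNF, and without the variance trend 9 for the antibody, 1 against TNF and 0 between the agonists. Counted as probe sets there were 36 for the antibody, 480 for the combination, 2 against TNF and 4 between the agonists, and on the numbers 1 to 3 there were 5 between the agonists. With a pseudocount of 36, a larger constant that shrinks differences of low signals, 45 genes were 2-fold apart at 2 h with the antibody, and 182 and 65 at 6 h with TNF and the antibody. The calls shared by the single agonists were 340 with the block. With divided controls they were 0 at the lowest and highest, by construction, since the antibody then had 0 calls.

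The interferon-stimulated genes changed the direction of their test in the interaction on the numbers 1 to 3, with a median of 0.051 without (adjusted p = 0.5) and with the block (adjusted p = 0.655). The endothelial markers changed direction in the interaction on the numbers 1 to 3 (median 0.059, adjusted p = 0.913) and against TNF on those numbers with the block (median 0.067, adjusted p = 0.936). The named genes had 0 reversals. Calls of named genes were lost for 30 results with only the groups compared, 17 with scaling to equal medians, 14 without the variance trend, 12 without a filter, 9 on the numbers 1 to 3, 7 without a pseudocount, 4 after quantile normalization, 2 with the mean of a gene's probe sets and 1 with a pseudocount of 36. In the block 102 named results stayed on their side of the threshold and 27 passed it in addition, and of 59 list calls 53 held. After quantile normalization 53 list calls held, with an estimated correlation 29 and with fry 32. Without a filter 53 held, with scaling to equal medians 56, with a filter on the mean 55 and without a pseudocount 58. On the numbers 1 to 3, 55 held without and 52 with the block.

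List calls were also lost when single arrays were left out, with C, L, T and B for the control, antibody, TNF and combination arrays and their numbers, and the adjusted p in parentheses. For the antibody these were the adipocyte markers without C1 (0.266), L0 (0.0714), L2 (0.0844) or L3 (0.125) and the contractile genes without C2 (0.262) or L0 (0.14). For TNF they were the cell cycle genes without C0 (0.285), T1 (0.319) or T3 (0.361), the contractile genes without C2 (0.202) or T0 (0.0865) and the TNF superfamily without C1 (0.212), C2 (0.0836), T0 (0.0552) or T3 (0.325). For the combination they were the TNF superfamily without C1 (0.119), C2 (0.0522) or B3 (0.215), the adipocyte markers without C1 (0.0749) or B2 (0.0527) and the matrix genes without B2 (0.0504). Against TNF they were the organizer genes without T3 (0.0548) or B1 (0.129), the cell cycle genes without T1 (0.447), T3 (0.518) or B2 (0.885), the matrix genes without T1 (0.11) or B2 (0.0601), the contractile genes without T2 (0.0676), T3 (0.112) or B1 (0.657) and the endothelial markers without T0 (0.931), T1 (0.0516), B2 (0.116) or B3 (0.181). Against the antibody they were the NF-kB subunits without L3 (0.0522) or B2 (0.164), the TNF superfamily without B3 (0.204), the matrix genes without B2 (0.0947), the contractile genes without L2 (0.1), L3 (0.145) or B1 (0.612) and the endothelial markers without L0 (0.618), B2 (0.0859) or B3 (0.0922). For the interaction they were the endothelial markers without C1 (0.0771), C2 (0.421), C3 (0.194), L0 (0.879), T0 (0.983), T1 (0.0765), B2 (0.184) or B3 (0.187), beside those of the interferon and NF-kB target genes given with these lists.

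Leaving out each array gave ranges of 6 to 27 for the antibody, 21 to 50 for TNF, 166 to 316 for the combination, 0 to 5 against TNF, 7 to 59 against the antibody, 0 to 3 between the agonists and 0 to 1 for the interaction. Counts moved by more than 1.5 times as follows, with the same letters. For the antibody: 27 without C0, 7 without C1 or L2, 9 without C2, T1 or B2, 6 without C3, L1 or L3, and 10 without T2. For TNF: 26 without C1, C2 or T2, 21 without T1 and 27 without T3. For the combination: 195 without C2, 166 without B1 and 169 without B2. Against TNF: 3 without C1 or L1, 1 without C2, C3, L2 or L3, and 0 without B1, B2 or any TNF array. Against the antibody: 24 without L0, 27 without L1, 23 without L2, 7 without B1 and 12 without B2. Between the agonists: 0 without C3 or any L or B array, or T1, T2 or T3. For the interaction: 1 without C0. With the block, for the antibody: 357 without C1, 288 without L0, 308 without L1 and 374 without L3. For TNF: 483 without C1 or T2, 468 without T1 and 462 without T3. Against TNF: 431 without T1, 397 without B1 and 345 without B2. Against the antibody: 450 without L1, 441 without L3, 398 without B1 and 354 without B2. Between the agonists: 53, 41, 42 and 59 without L0 to L3, and 32, 47 and 52 without T1 to T3. For the interaction: 11 without C0 and 4 without T0. Signals near the background limit the smallest changes that can be measured.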

Other observations

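Genes outside the fixed lists, chosen after their values were seen, also changed with both agonists against the control at 24 h. Il18bp, which encodes a decoy protein that binds interleukin-18, rose by 2.38 ± 0.31 (adjusted p = 0.000608), Ifi47, an interferon-inducible GTPase gene, by 2.11 ± 0.19 (adjusted p = 2.7e-05), and the guanylate-binding protein gene Gbp7 by 2.14 ± 0.27 (adjusted p = 0.000436), whose probe sets can cross-hybridise with related genes. The receptor genes Ifngr1 and Ifngr2 for interferon gamma rose by 1.02 ± 0.18 and 1.06 ± 0.15. Gsdmd, which encodes the pore-forming substrate of inflammatory caspases, rose by 1.20 ± 0.20 (adjusted p = 0.0053), and Casp4 by 2.04 ± 0.16 (adjusted p = 1.61e-05). Scube3, a secreted signalling protein gene, rose by 3.42 ± 0.60, the guidance factor gene Ntn1 by 1.72 ± 0.24, and the hyaluronan receptor gene Cd44 by 0.89 ± 0.20.

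Among the falls, Mthfd2, a mitochondrial folate enzyme gene, changed by -0.71 ± 0.16 and Cars, a cysteinyl-tRNA synthetase gene, by -0.39 ± 0.09 (adjusted p = 0.0286 and 0.0383). Id2, which like Id4 encodes an inhibitor of basic helix-loop-helix factors, changed by -0.75 ± 0.18 (adjusted p = 0.0477). The cytoskeletal genes Csrp1 and Myh10 changed by -0.50 ± 0.09 and -0.52 ± 0.12, and the protease gene Pappa by -0.97 ± 0.15 (adjusted p = 0.0028).

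The markers of macrophages were highest on the arrays numbered 3 at 24 h. C1qa had a mean signal of 231.8 there and 7.40 to 9.70 on the other numbers, C1qb had 476.9, and Lyz2 had 1441. At 2 h and 6 h, on arrays numbered 0, the endothelial markers Pecam1 and Emcn had mean signals of 4217 and 8276. Sele had a mean signal of 778.4 on the 24 h arrays numbered 0.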
